A study of Mus musculus with 24 samples.

How the data were processed

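Bulk RNA-seq libraries of 4 mouse tumour cell lines were compared. MC38 is a colon adenocarcinoma line, LLC1 a Lewis lung carcinoma line, AKR an esophageal carcinoma line and Hepa1-6 a hepatocellular carcinoma line. Per the labels, each line carried a single guide RNA against B2m (sgB2m), which encodes the light chain of MHC class I, or a non-targeting guide (sgNT). Each line and guide had 3 libraries, which made 8 groups and 24 libraries. Per the labels' protocols, cells grew in DMEM with serum, and strand-specific paired-end libraries were made from total RNA. The labels give no sequencing batch and do not say whether the 3 replicates of a group were separate cultures, or whether the edited cells were clones or pools. The p-values therefore measure the spread between these 3 libraries per group.

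The deposited values are log2 normalised counts, in 1 table per line. Per the submitters' processing notes, FastQC 0.11.5, STAR and DESeq2 were used with the mouse build mm10. The sources used here give no version of STAR or DESeq2, and do not give the gene counter, its annotation or whether it used the strand of the reads. Each library's values, returned to the linear scale after removal of a pseudocount of 1, were whole multiples of 1 step, within 0.05 reads for 100% of the values. The deposited unit was therefore taken as log2(count divided by 1 size factor + 1), with the size factors set within each line. Levels can be compared between the 6 libraries of a line, while levels in different lines come from separate normalisations. Genes at 0 in all 6 libraries of a line have no entry in its table. Reads counted per gene summed to between 25 and 49.7 M per library. A normalisation of this kind assumes that most genes do not change in a shared direction. Because a constant was added before the logarithm, fold changes of weakly expressed genes are drawn toward 0. Counts without strand would mix the reads of a gene and of an antisense partner, and the reads of near-identical family members can be split or lost.

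Statistics were computed in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Within each line, genes with a log2 value of at least 3.5 in at least 3 of the 6 libraries were tested, whichever group the 3 belonged to. The change of a gene was the mean log2 value in sgB2m minus that in sgNT, with no covariate, tested by limma's two-sided moderated test with an intensity trend. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in the line, and a gene was called at an adjusted p under 0.05. A count of calls with an absolute log2 fold change of at least 1, which is 2-fold, was also taken. Values after a gene name are log2 fold changes ± standard error from this fit, with 3 libraries per group. Mean normalised counts are given ± SD. Reads are counts recovered from the deposited values and summed over the 3 libraries of a group. Where a group had 0 reads, the fold is a lower bound computed against 3 reads per library, and such bounds and read numbers cover counting error only.

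A total of 29 gene lists was fixed before the data were examined. They covered MHC class I heavy chains, MHC class I peptide loading, the MHC class II pathway, chemokines, cytokines, the type I interferon response, interferon-gamma GTPases and regulators, NK cell ligands, and co-stimulatory and checkpoint ligands. Others covered NF-kB targets, endoplasmic reticulum (ER) chaperones and degradation, the ATF4 amino acid response, p53 targets, cell cycle and DNA replication, mesenchymal and matrix genes, epithelial genes, hypoxia and glycolysis, cholesterol synthesis, NRF2 targets, iron handling, immediate early and heat shock genes, and transcripts of the mitochondrial genome. The rest were markers of squamous epithelium, hepatocytes, intestinal epithelium, alveolar epithelium, myeloid cells, T and NK cells, and endothelial cells. B2m was left out of every list. Lists with at least 5 tested members were tested against all other genes by limma's camera with a preset correlation of 0.01, and adjusted over the lists of the line. Each list test was repeated with a correlation estimated from the data, and the count of called members was also taken with p-values adjusted over the list alone.

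Across lines, 3 results were taken over the genes tested in all 4. The first was limma's moderated test of the 4 log2 fold changes, with the line as the replicate. The next was the number of genes called in the same direction in all 4 lines, set beside the number that independent lists would share. The last was an F test of the interaction between line and guide in a model of all 24 libraries, in which any offset between the separately normalised tables cancels. Lists were also compared between pairs of lines with camera on that interaction, with adjustment over 120 tests.

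The named genes followed a rule fixed before the data were examined. B2m and Cxcl16 were named in every line. In each line the 6 highest and 6 lowest fold changes were named among called genes with a mean log2 value of at least 6 in the higher group, no overlap between groups and a symbol other than that of a predicted gene or clone. Called members of the MHC class I lists and the chemokine list were named where the absolute log2 fold change was at least 0.58. Of each other list that passed camera, the 3 called members with the largest change in the direction of the list were named. Across lines, up to 8 genes per direction called in all 4 lines were named. In AKR, 1 gene that the rule names is not reported here. Coordinates are 1-based and come from GENCODE release M21 on the build that mm10 denotes, in which 34787 of the 34866 gene identifiers in the tables (99.8%) were found.

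The steps were tested on simulated data before use. Counts were drawn for the real genes with changes of 1.5-fold, 2-fold and 4-fold in a set of genes. In MC38, 91% of the genes changed by 1.5-fold and 98.5% of those changed by 2-fold were called. In LLC1 these shares were 89.6% and 95.5%, in AKR 88.1% and 95.4%, and in Hepa1-6 91% and 98.5%. Of the calls, 3.37% were false in MC38, 3.62% in LLC1, 4.11% in AKR and 4.02% in Hepa1-6. For changes that differed between lines, 82.1% of genes changed by 1.5-fold and 92.3% of those changed by 2-fold were called. Genes were drawn independently with 1 dispersion per line, from 0.00222 in LLC1 to 0.00427 in MC38. Far fewer genes were changed than were called in the real data, so these shares may not hold for the real calls.

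Alternatives fixed before the data were examined were no filter, a stricter filter at a log2 value of 6, a pseudocount of 8, quantile normalisation, median centring, the moderated test without the trend or in its robust form, and limma's voom on the recovered reads. Others were a test against 2-fold, the replicate number as a block, camera with an estimated correlation, limma's fry, and leaving out each library in turn. After the data were examined, MC38 was also analysed without the genes of chromosomes 1 and 18. None of the columns in the tables was left out.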

Results

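Loss of MHC class I was modelled by editing B2m, the gene of beta-2-microglobulin, in 4 mouse tumour cell lines, and bulk RNA-seq was used to ask what else changed in the tumour cells. For each of MC38, LLC1, AKR and Hepa1-6, 3 sgB2m libraries were compared with 3 sgNT libraries. Reads counted per library ranged from 33.3 to 38.3 M in MC38 sgB2m and from 28.4 to 49.7 M in MC38 sgNT. The ranges were 27.4 to 27.9 and 26.1 to 28.1 M in LLC1, 29.7 to 32.2 and 28.3 to 32.9 M in AKR, and 25 to 27.6 and 26 to 35.4 M in Hepa1-6, for sgB2m and sgNT in turn. Mitochondrial transcripts took 3.34% ± 0.04 of the reads in sgB2m and 3.16% ± 0.078 in sgNT of MC38 (SD, n = 3), and 4.52% ± 0.083 and 4.43% ± 0.056 in LLC1. They took 4.03% ± 0.012 and 3.52% ± 0.026 in AKR, and 4.19% ± 0.11 and 5.09% ± 0.11 in Hepa1-6.

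The lines kept markers of their origin to different degrees, and each also expressed markers of other tissues. Of 21 hepatocyte markers, 15 had a mean log2 value of at least 6 in Hepa1-6, led by Afp at 17.6 and Alb at 17, against 2 in AKR and 0 in MC38 and LLC1. Of the 20 squamous markers, 4 reached that level in AKR, led by Krt13 at 8.27 and Sox2 at 8.18. MC38 had 3, led by Krt14 at 10.9, LLC1 had 0, and Hepa1-6 had 5, led by Sprr1a at 13.5. Of the 15 intestinal markers, 1 reached it in MC38, which was Lgals4 at 6.73, 2 in LLC1, 3 in AKR and 5 in Hepa1-6, where Cdh17 stood at 14.6. Of the 11 alveolar markers, LLC1 had 2, Abca3 at 10.3 and Napsa at 7.7, and each other line had 1, which was Abca3. Among markers of T and NK cells, the highest mean log2 value in any line was 6.18, for Lck in AKR. Myeloid markers with a mean of at least 6 numbered 2 in MC38, 3 in LLC1, 2 in AKR and 3 in Hepa1-6, and were led by Cd68 or Cd14. Endothelial markers at that level numbered 3 in MC38, 1 in LLC1, 3 in AKR and 3 in Hepa1-6.

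B2m, the edited gene, fell in all 4 lines and was reduced, not absent. B2m (ENSMUSG00000060802) lies on the plus strand of chromosome 2 at 122147686 to 122153083 (mm10). Its normalised count was 9462 ± 284 in MC38 sgB2m and 32420 ± 1240 in sgNT (SD, n = 3), a log2 fold change of -1.78 ± 0.042 (SE, adjusted p = 2.54e-09). In LLC1 it was 5045 ± 118 against 16560 ± 181 (-1.71 ± 0.029, adjusted p = 1.8e-14). In AKR it was 4309 ± 334 against 12820 ± 336 (-1.57 ± 0.054, adjusted p = 2.25e-08), and in Hepa1-6 2574 ± 112 against 6578 ± 87.8 (-1.35 ± 0.04, adjusted p = 7.52e-13). The decrease was 3.43-fold in MC38, 3.28-fold in LLC1, 2.98-fold in AKR and 2.56-fold in Hepa1-6, and its size differed between lines (interaction adjusted p = 1.13e-05). A count over the whole gene does not show whether the remaining transcripts carry an edit. The direction of B2m matched the guide in each of the 24 libraries.

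Cxcl16, the ligand of the lymphocyte receptor CXCR6 and the gene in the title of the series, fell in 3 lines and rose in Hepa1-6. Cxcl16 (ENSMUSG00000018920) lies on the minus strand of chromosome 11 at 70453983 to 70459984. It fell 1.61-fold in MC38, from 663.1 ± 52.2 to 412.1 ± 56 normalised counts (-0.69 ± 0.12, adjusted p = 0.00176). In LLC1 it fell 2.08-fold, from 136.1 ± 38.5 to 63.17 ± 3.58 (-1.06 ± 0.22, adjusted p = 0.00115). In AKR it was weakly expressed and fell 3.97-fold, from 28.66 ± 8.68 to 6.62 ± 2.64 (-1.99 ± 0.45, adjusted p = 0.00433), on 84 reads in sgNT and 20 in sgB2m. Its size there depends on the pseudocount, with a log2 fold change of -1.32 at a pseudocount of 8. In Hepa1-6 it rose 3.06-fold, from 814.4 ± 95.3 to 2484 ± 56.1 (1.61 ± 0.075, adjusted p = 1.69e-10). The change differed between lines (interaction adjusted p = 1.32e-08). In AKR the gene was not tested under the stricter filter, and it no longer passed the filter in 3 of the 6 runs that left out a library.

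**Figure D1:**
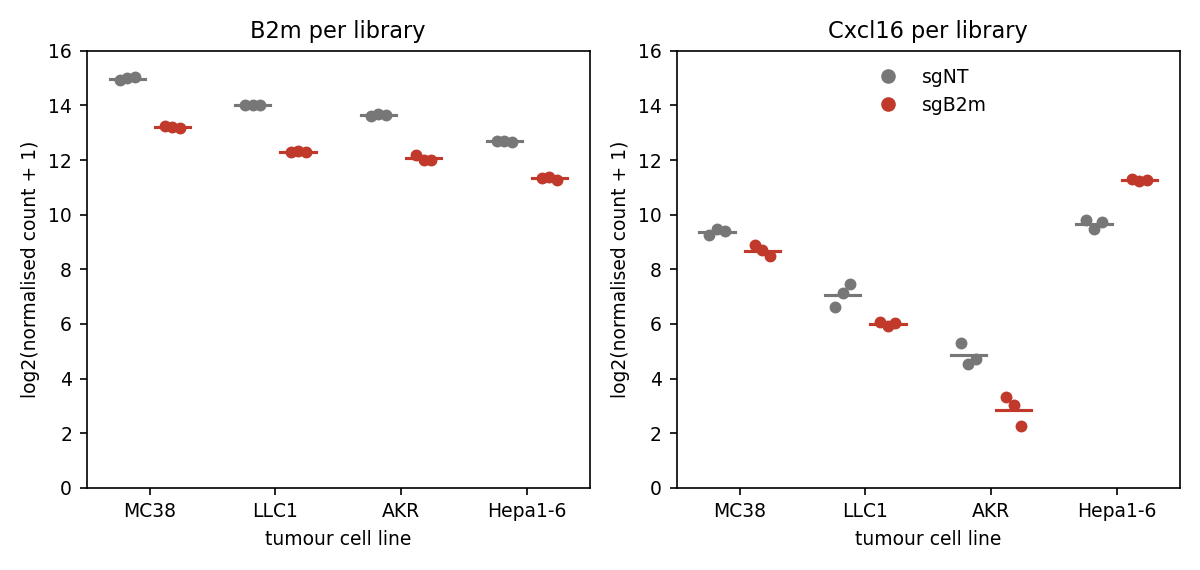
Values of B2m and Cxcl16 per library, as log2(normalised count + 1) on the vertical axis and cell line on the horizontal axis; each point is a library, grey for sgNT and red for sgB2m, and bars are means of 3 libraries. B2m was lower in sgB2m in every line (log2 fold changes of -1.78 in MC38, -1.71 in LLC1, -1.57 in AKR and -1.35 in Hepa1-6), while Cxcl16 was lower in MC38, LLC1 and AKR and higher in Hepa1-6.

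In MC38 sgB2m cells, camera called type I interferon genes, interferon-gamma GTPases, NF-kB targets, MHC class I peptide loading, the ATF4 response and cholesterol synthesis as rising, and hypoxia and glycolysis genes as falling. With an estimated correlation the type I interferon call held (adjusted p = 0.0407) and the other 6 did not (0.0663 to 0.272). The acute-phase gene Lcn2 rose 18.5-fold and the complement gene C3 rose 6.86-fold. Of 16532 genes tested, 2636 rose and 2615 fell, and 574 rose and 405 fell by at least 2-fold. The groups did not overlap in 45% of the tested genes, against 10% by chance for 3 libraries against 3. The median absolute log2 fold change of called genes was 0.415.

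Type I interferon genes passed with the lowest camera p of the lists tested in MC38. In that list 26 of 38 tested members rose, 1 fell and 11 did not pass (28 rose and 2 fell adjusted over the list alone), with a median of 0.62 (camera adjusted p = 2.81e-09, and adjusted p = 0.0407 with an estimated correlation). Its leading members were Ifi44 (3.53 ± 0.78), the nucleic acid sensor Zbp1 (2.50 ± 0.51) and Ifit3b (1.99 ± 0.34), with adjusted p of at most 0.00701. Of the interferon-gamma GTPases and regulators, 16 of 24 tested members rose and 8 did not pass (16 rose adjusted over the list alone, with camera adjusted p = 2.42e-05, and adjusted p = 0.164 with an estimated correlation). The immunity-related GTPases Tgtp2 (1.75 ± 0.31) and Irgm2 (1.67 ± 0.13) and the guanylate-binding protein Gbp6 (1.57 ± 0.29) led that list (adjusted p at most 0.00262). Of the NF-kB targets, 11 of 22 tested members rose, 2 fell and 9 did not pass (12 rose and 3 fell adjusted over the list alone, with camera adjusted p = 0.00104, and adjusted p = 0.272 with an estimated correlation). These included the neutrophil chemokine Cxcl5 (6.88 ± 0.69), the iron-binding protein Lcn2 (4.21 ± 0.23) and C3 (2.78 ± 0.057), with adjusted p of at most 6.39e-05. Ifit3b, Tgtp2 and Gbp6 have close paralogs whose reads can be confused with theirs.

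MHC class I genes other than B2m moved in both directions in MC38. For peptide loading, 8 of 16 tested members rose and 8 did not pass (8 rose adjusted over the list alone, with camera adjusted p = 0.00442, and adjusted p = 0.164 with an estimated correlation), and the peptide-trimming aminopeptidase Erap1 (0.73 ± 0.072) was its member past a log2 change of 0.58 (adjusted p = 5.77e-05). For the heavy chains, 7 of 16 tested members rose, 1 fell and 8 did not pass (7 rose and 2 fell adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0568). The lipid-presenting Cd1d1 (1.71 ± 0.34), H2-T10 (0.74 ± 0.20) and the iron regulator Hfe (0.62 ± 0.11) rose, and H2-T23 (-0.74 ± 0.13), the Qa-1 heavy chain, fell (adjusted p at most 0.0197). The classical heavy chains H2-K1 (0.23 ± 0.05) and H2-D1 (0.37 ± 0.054), picked after their values were seen, also rose (adjusted p at most 0.00655). Heavy-chain genes are near-identical, so their reads are uncertain between members. The call of H2-T10 ended without sgB2m replicate 3 (adjusted p = 0.0771) and without sgNT replicate 2 (adjusted p = 0.0693). Among chemokines, 5 of 16 tested members rose, 2 fell and 9 did not pass (5 rose and 3 fell adjusted over the list alone), and the list did not pass camera (adjusted p = 0.514). Cxcl5, Cx3cl1 (1.02 ± 0.091) and Ccl9 (1.87 ± 0.13) rose and Cxcl16 fell (adjusted p at most 0.00176).

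Metabolic lists also moved in MC38. Hypoxia and glycolysis genes fell: 17 of 23 tested members fell, 2 rose and 4 did not pass (17 fell and 3 rose adjusted over the list alone), with a median of -0.34 (camera adjusted p = 1.61e-05, and adjusted p = 0.18 with an estimated correlation). The hypoxia-induced Ankrd37 (-1.30 ± 0.39), the lactate transporter Slc16a3 (-0.69 ± 0.065) and the mitophagy receptor Bnip3 (-0.63 ± 0.057) led the fall (adjusted p at most 0.0282). Cholesterol synthesis genes rose, and 13 of 24 tested members rose and 11 did not pass (16 rose adjusted over the list alone), with a median of 0.15 (camera adjusted p = 1.1e-05, and adjusted p = 0.0663 with an estimated correlation). They were led by the sterol isomerase Ebp (0.75 ± 0.064), the sterol dehydrogenase Nsdhl (0.53 ± 0.045) and the sterol-sensing Insig1 (0.47 ± 0.036) (adjusted p at most 2.18e-05). Of the ATF4 amino acid response, 10 of 24 tested members rose, 2 fell and 12 did not pass (11 rose and 2 fell adjusted over the list alone, with camera adjusted p = 0.00291, and adjusted p = 0.272 with an estimated correlation). Its leading members were Stc2 (1.41 ± 0.083), Vldlr (0.99 ± 0.063) and the cysteine-forming enzyme Cth (0.67 ± 0.13) (adjusted p at most 0.00329). The call of Ankrd37 ended in 4 of 6 runs that left out a library, with adjusted p of 0.0724 and 0.053 without sgB2m replicates 1 and 3, and of 0.0713 and 0.0943 without sgNT replicates 2 and 3. It also ended without the filter (adjusted p = 0.0618) and without the trend (adjusted p = 0.0949), and that of H2-T10 without the trend (adjusted p = 0.0604).

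Among MC38 genes with a mean log2 value of at least 6 in the higher group, no overlap between groups and a symbol other than that of a predicted gene or clone, the highest and lowest changes included genes with 0 reads in 1 group. The purine deaminase Gda had 0 reads in sgNT and 582 in sgB2m, and was at least 68.8-fold higher. The other highest changes were Nxf3 (7.10 ± 0.74), Cxcl5, the cortisone reductase Hsd11b1 (6.06 ± 0.79), the asparaginase Aspg (6.04 ± 0.32) and the inflammasome gene Nlrp2 (5.88 ± 0.27) (adjusted p at most 0.000343). The arginine transporter Slc7a2 fell 306-fold on 34 remaining reads, from 3740 ± 454 to 11.89 ± 5.68 normalised counts (-8.26 ± 0.26, adjusted p = 2.18e-08). Its neighbour on chromosome 8, Pdgfrl, had 456 reads in sgNT and 0 in sgB2m, and was at least 46.2-fold lower. The Wnt antagonist Nkd2 and the cap-binding protein Eif4e3 also had 0 reads in sgB2m, and were at least 35.1-fold and 23.2-fold lower. The protocadherin Pcdhgb4 (-7.40 ± 0.63), whose cluster shares exons between genes, and the ubiquitin ligase Pdzrn3 (-7.40 ± 0.73) completed the lowest 6 (adjusted p at most 6.06e-05).

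Changes in MC38 varied with the position of the genes. The median log2 fold change was 0.23 for 1013 genes of chromosome 1 and -0.21 for 437 genes of chromosome 18. Without the genes of these chromosomes, an alternative added after the data were examined, 4580 genes were called and the 7 lists still passed camera. The 17 other lists tested had adjusted p between 0.0568 and 0.963. They were those of MHC class II, heavy chains, chemokines, cytokines, NK cell ligands, co-stimulatory and checkpoint ligands, ER chaperones, p53 targets, cell cycle, mesenchymal, epithelial, squamous and endothelial genes, NRF2 targets, iron handling, immediate early genes and mitochondrial transcripts. Among these, median, mean and test differed in sign for chemokines, checkpoint ligands, ER chaperones, p53 targets, squamous markers and NRF2 targets. The hepatocyte, intestinal, alveolar, myeloid, and T and NK lists had fewer than 5 tested members.

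In LLC1 sgB2m cells, cholesterol synthesis and type I interferon genes rose, while the ATF4 response, ER chaperones, chemokines, cytokines, NF-kB targets, p53 targets and immediate early genes fell. With an estimated correlation the calls of cholesterol synthesis and the ATF4 response held (adjusted p = 0.0221 for both) and the other 7 did not (0.0812 to 0.154). In the cholesterol list 24 of 24 tested members rose (24 rose adjusted over the list alone), with a median of 1.43 (camera adjusted p = 3.39e-29, and adjusted p = 0.0221 with an estimated correlation). The synthase Hmgcs1 (2.05 ± 0.035) rose 4.13-fold, from 3473 ± 83.1 to 14350 ± 512 normalised counts, and Idi1 (1.90 ± 0.041) and Acat2 (1.85 ± 0.046) rose 3.74-fold and 3.61-fold (adjusted p at most 9.95e-13). Of 15323 genes tested, 3169 rose and 3334 fell, and 333 rose and 314 fell by at least 2-fold. The groups did not overlap in 51.8% of the genes, against 10% by chance. The median absolute log2 fold change of called genes was 0.37.

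The ATF4 response had the lowest camera p of the falling lists in LLC1. Of the ATF4 amino acid response, 21 of 25 tested members fell, 1 rose and 3 did not pass (22 fell and 1 rose adjusted over the list alone), with a median of -0.61 (camera adjusted p = 1.11e-12, and adjusted p = 0.0221 with an estimated correlation). The glutathione-degrading Chac1 (-1.61 ± 0.083), the phosphatase subunit Ppp1r15a (-1.22 ± 0.054) and Atf3 (-1.09 ± 0.082) led it (adjusted p at most 1.12e-07). Of the ER chaperones and degradation genes, 12 of 19 tested members fell, 1 rose and 6 did not pass (12 fell and 1 rose adjusted over the list alone, with camera adjusted p = 0.000203, and adjusted p = 0.127 with an estimated correlation). The chaperone Hspa5 (-0.79 ± 0.025) fell from 53040 ± 1400 to 30690 ± 634 normalised counts, beside Herpud1 (-0.66 ± 0.051) and Hyou1 (-0.51 ± 0.033) (adjusted p at most 1.32e-07). Of the immediate early and heat shock genes, 10 of 18 tested members fell, 3 rose and 5 did not pass (11 fell and 3 rose adjusted over the list alone, with camera adjusted p = 0.01, and adjusted p = 0.127 with an estimated correlation), with Egr1 (-1.25 ± 0.064), Myc (-1.24 ± 0.038) and Ier2 (-1.03 ± 0.087) in front (adjusted p at most 3.77e-07). The p53 targets fell by a narrow margin, and 12 of 22 tested members fell, 4 rose and 6 did not pass (12 fell and 5 rose adjusted over the list alone, with camera adjusted p = 0.0497, and adjusted p = 0.154 with an estimated correlation). Its leading members were Eda2r (-2.45 ± 0.20) and the death genes Pmaip1 (-2.01 ± 0.25) and Aen (-1.15 ± 0.07) (adjusted p at most 1.49e-05). That list lost its call with the stricter filter (adjusted p = 0.0751), quantile normalisation (0.0503), median centring (0.0521) or the replicate block (0.0583), and without sgB2m replicate 3 (0.0516) or sgNT replicate 2 (0.0597).

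Chemokines fell in LLC1 at the preset correlation. Of the chemokines, 8 of 17 tested members fell, 1 rose and 8 did not pass (8 fell and 1 rose adjusted over the list alone), with a median of -0.56 (camera adjusted p = 0.000936, and adjusted p = 0.0812 with an estimated correlation). Besides Cxcl16, the falls of at least 0.58 on the log2 scale were Cxcl12 (-3.42 ± 0.32), Ccl20 (-1.72 ± 0.14), Cxcl2 (-1.51 ± 0.17), Ccl7 (-1.09 ± 0.061) and Ccl2 (-0.85 ± 0.032) (adjusted p at most 6.59e-06). The monocyte chemokine Ccl2 went from 9591 ± 177 to 5335 ± 125 normalised counts, and Ccl9 (1.06 ± 0.33) rose (adjusted p = 0.0176). Of the cytokines, 7 of 13 tested members fell, 1 rose and 5 did not pass (7 fell and 1 rose adjusted over the list alone, with camera adjusted p = 0.0061, and adjusted p = 0.127 with an estimated correlation), led by Il6 (-1.61 ± 0.45), Il11 (-1.46 ± 0.41) and the angiogenic factor Vegfa (-1.17 ± 0.05) (adjusted p at most 0.0105). Of the NF-kB targets, 12 of 22 tested members fell, 2 rose and 8 did not pass (12 fell and 2 rose adjusted over the list alone, with camera adjusted p = 0.000989, and adjusted p = 0.0812 with an estimated correlation), with Ccl20, Il6 and Cxcl2 as the leading members. In the type I interferon list 14 of 30 tested members rose, 1 fell and 15 did not pass (15 rose and 2 fell adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.000221, and adjusted p = 0.0812 with an estimated correlation). The antiviral Ifit3b (2.73 ± 0.71), Ifit3 (2.11 ± 0.24) and Ifit1 (1.74 ± 0.47), which share sequence with each other, led it (adjusted p at most 0.00859).

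The MHC class I lists did not pass camera in LLC1. For heavy chains 6 of 13 tested members rose, 2 fell and 5 did not pass (6 rose and 2 fell adjusted over the list alone, with camera adjusted p = 0.403), and for peptide loading 5 of 16 tested members fell, 3 rose and 8 did not pass (5 fell and 3 rose adjusted over the list alone, with camera adjusted p = 0.725). Cd1d1 (1.22 ± 0.31), the neonatal Fc receptor Fcgrt (0.69 ± 0.064) and H2-T10 (0.59 ± 0.21) rose, and the immunoproteasome subunit Psmb8 (-3.38 ± 0.82) fell, on 63 reads in sgNT and 9 in sgB2m (adjusted p at most 0.0408). The classical H2-D1 (-0.39 ± 0.032) fell (adjusted p = 2.69e-07), and H2-K1 (-0.074 ± 0.057) did not pass the test (adjusted p = 0.327); both were picked after their values were seen. The call of H2-T10 ended without any of the sgB2m replicates 1 and 3 or sgNT replicates 1 and 2, with adjusted p from 0.0616 to 0.139, and that of Ccl9 ended without sgB2m replicate 2 (0.053) or sgNT replicate 3 (0.069). Without the filter, the calls of H2-T10 (adjusted p = 0.0813), Ccl9 (0.0861), Il11 (0.0656) and Ifit1 (0.0781) ended, as did without the trend those of Ccl9 (0.0711), Il11 (0.0581), Ifit1 (0.0774) and Ifit3b (0.0521).

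Among LLC1 genes that met the same limits on expression, overlap and symbol, the highest changes were Klhl4 (3.91 ± 0.29), the immunoglobulin constant region Ighm (3.47 ± 0.10), the matrix protein Aspn (3.34 ± 0.42), Mrgprf (2.36 ± 0.33) and the signal recognition particle RNAs Rn7s2 (2.33 ± 0.27) and Rn7s1 (2.32 ± 0.27), which are near-identical copies (adjusted p at most 4.19e-05). The lowest of these genes was the collagenase Mmp13, which fell from 163.2 ± 14 to 1.276 ± 2.21 normalised counts (-6.60 ± 0.56), an uncertain size since the SD in sgB2m exceeds the mean. Among them it was followed by Ptgfrn (-3.53 ± 0.33), the surface sialomucin Cd34 (-3.44 ± 0.33), Cxcl12, Vopp1 (-3.32 ± 0.15) and the stromelysin Mmp3 (-2.66 ± 0.35) (adjusted p at most 2.75e-05). The 13 other lists tested had adjusted p between 0.0774 and 0.995. They were those of both MHC class I parts, MHC class II, interferon-gamma GTPases, NK cell ligands, checkpoint ligands, cell cycle, mesenchymal and epithelial genes, hypoxia, NRF2 targets, iron handling and mitochondrial transcripts. Median, mean and test differed in sign for MHC class II, checkpoint ligands, mesenchymal and epithelial genes and NRF2 targets. The squamous, hepatocyte, intestinal, alveolar, myeloid, endothelial, and T and NK lists had fewer than 5 tested members.

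In AKR sgB2m cells, epithelial and squamous genes, p53 targets and antioxidant NRF2 targets rose, and the ATF4 response and ER chaperones fell. With an estimated correlation, 0 of the 11 lists called in AKR by camera passed (lowest adjusted p = 0.185). Unadjusted camera p-values at the preset correlation were at most 0.0146 for these lists, and limma's fry passed each of them. Fry tests each list by itself and also passed lists that camera did not call, such as chemokines (camera adjusted p = 0.4, fry adjusted p = 0.000198). Passing fry therefore adds little for these 11 lists. Of 15882 genes tested, 3332 rose and 3483 fell, and 436 rose and 373 fell by at least 2-fold. The groups did not overlap in 52.5% of the genes, against 10% by chance. The median absolute log2 fold change of called genes was 0.402.

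The ATF4 amino acid response fell with the lowest camera p of the lists tested in AKR, where 22 of 24 tested members fell, 1 rose and 1 did not pass (23 fell and 1 rose adjusted over the list alone), with a median of -0.54 (camera adjusted p = 1.07e-12, and adjusted p = 0.185 with an estimated correlation). The starvation hormone Fgf21 (-1.95 ± 0.10), Atf3 (-1.24 ± 0.042) and the folate enzyme Aldh1l2 (-1.08 ± 0.071) led it (adjusted p at most 1.11e-06). Of the ER chaperones and degradation genes, 13 of 20 tested members fell, 1 rose and 6 did not pass (14 fell and 2 rose adjusted over the list alone, with camera adjusted p = 9.63e-06, and adjusted p = 0.204 with an estimated correlation). The degradation factors Herpud1 (-1.20 ± 0.037) and Sel1l (-0.96 ± 0.043) and the chaperone Dnajb9 (-0.77 ± 0.055) were its leading members (adjusted p at most 2.03e-06). Of the hypoxia and glycolysis genes, 8 of 22 tested members fell, 1 rose and 13 did not pass (9 fell and 1 rose adjusted over the list alone, with camera adjusted p = 0.0214, and adjusted p = 0.454 with an estimated correlation), with Ankrd37 (-1.46 ± 0.21), Vegfa (-0.69 ± 0.035) and Pdk1 (-0.68 ± 0.042) in front (adjusted p at most 0.000264). That list lost its call under quantile normalisation (adjusted p = 0.176).

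The p53 targets had the lowest camera p of the rising lists in AKR. Of the p53 targets, 12 of 23 tested members rose, 2 fell and 9 did not pass (12 rose and 2 fell adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.00103, and adjusted p = 0.204 with an estimated correlation). They were led by Phlda3 (1.49 ± 0.082), the cyclin Ccng1 (1.23 ± 0.044) and Zmat3 (1.16 ± 0.054) (adjusted p at most 3.45e-07). Of the NRF2 targets, 10 of 15 tested members rose, 3 fell and 2 did not pass (11 rose and 3 fell adjusted over the list alone, with camera adjusted p = 0.00342, and adjusted p = 0.185 with an estimated correlation), with the quinone reductase Nqo1 (1.25 ± 0.045), Srxn1 (0.80 ± 0.049) and Taldo1 (0.52 ± 0.059) (adjusted p at most 5.05e-05). Of the cholesterol genes, 15 of 25 tested members rose, 4 fell and 6 did not pass (15 rose and 4 fell adjusted over the list alone, with camera adjusted p = 0.00196, and adjusted p = 0.185 with an estimated correlation), with Dhcr7 (1.17 ± 0.086), Mvd (0.81 ± 0.093) and Hsd17b7 (0.79 ± 0.09) (adjusted p at most 5.18e-05). Of the epithelial genes, 8 of 10 tested members rose, 1 fell and 1 did not pass (8 rose and 1 fell adjusted over the list alone, with camera adjusted p = 0.0067, and adjusted p = 0.256 with an estimated correlation), with the transcription factor Grhl2 (0.91 ± 0.10), the adhesion molecule Epcam (0.76 ± 0.24) and the protease inhibitor Spint1 (0.75 ± 0.091) (adjusted p at most 0.0239). Of the squamous markers, 5 of 7 tested members rose, 1 fell and 1 did not pass (5 rose and 1 fell adjusted over the list alone), with a median of 1.20 (camera adjusted p = 0.0315, and adjusted p = 0.213 with an estimated correlation). The keratin Krt16 (3.56 ± 0.73) and the cornified envelope proteins Sprr1b (3.22 ± 0.27) and Sprr1a (1.76 ± 0.15), which are paralogs, led them (adjusted p at most 0.00245). The squamous call ended without sgB2m replicate 1 (adjusted p = 0.0955), 2 (0.0556) or 3 (0.0746), with no filter (0.0698), the stricter filter (0.0875) or quantile normalisation (0.0523), and the epithelial call with no filter (0.0842). The call of Epcam ended without sgB2m replicate 1 (0.0541) or 3 (0.0956), without sgNT replicate 2 (0.0661) or 3 (0.0716), and with no filter (0.0536).

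The MHC class I heavy chains rose modestly in AKR, and peptide loading did not pass. For heavy chains 8 of 14 tested members rose, 2 fell and 4 did not pass (8 rose and 2 fell adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.0322, and adjusted p = 0.286 with an estimated correlation). Cd1d1 (0.66 ± 0.14) and Mr1 (0.60 ± 0.07), which presents vitamin B metabolites, rose, and H2-M5 (-1.43 ± 0.39) fell (adjusted p at most 0.0114). H2-K1 (0.33 ± 0.041) and H2-D1 (0.17 ± 0.04), picked after their values were seen, rose too (adjusted p at most 0.00517). For peptide loading 6 of 16 tested members rose, 5 fell and 5 did not pass (6 rose and 6 fell adjusted over the list alone, with camera adjusted p = 0.814), with the transporter Tap1 (0.61 ± 0.073) and the immunoproteasome subunit Psmb9 (0.92 ± 0.20) higher and the chaperone Tapbpl (-0.71 ± 0.084) lower (adjusted p at most 0.00408). In the type I interferon list 15 of 36 tested members rose, 4 fell and 17 did not pass (15 rose and 4 fell adjusted over the list alone, with camera adjusted p = 0.0331, and adjusted p = 0.204 with an estimated correlation), led by Oas3 (0.97 ± 0.077), Dhx58 (0.90 ± 0.089) and Oasl1 (0.78 ± 0.082) (adjusted p at most 3.12e-05). Of the interferon-gamma GTPases and regulators, 13 of 23 tested members rose, 4 fell and 6 did not pass (13 rose and 4 fell adjusted over the list alone, with camera adjusted p = 0.0315, and adjusted p = 0.311 with an estimated correlation), led by Gbp8 (2.33 ± 0.40), Tgtp2 (2.10 ± 0.41) and Ifi47 (1.76 ± 0.38) (adjusted p at most 0.00351). Under quantile normalisation the heavy chain (adjusted p = 0.0521), type I interferon (0.0945) and interferon-gamma (0.0523) lists lost their calls. So did, without sgB2m replicate 2, the type I interferon (0.0532) and interferon-gamma (0.0884) lists, the latter also with the stricter filter (0.206). Chemokines did not pass as a list, and 5 of 15 tested members rose, 3 fell and 7 did not pass (5 rose and 3 fell adjusted over the list alone, with camera adjusted p = 0.4). Ccl7 (1.97 ± 0.14), Ccl2 (1.30 ± 0.056), Cxcl1 (1.04 ± 0.046) and Ccl20 (0.82 ± 0.094) rose, and Ccl2 reached 11330 ± 831 normalised counts from 4594 ± 224 (adjusted p at most 5.18e-05).

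Among AKR genes that met the same limits on expression, overlap and symbol, the highest change was that of Trim69 (3.57 ± 0.27), the next annotated gene downstream of B2m on the same strand, at 122160700 to 122179027 of chromosome 2 (adjusted p = 3.15e-06). Trim69 rose also in Hepa1-6 (4.41 ± 0.63, adjusted p = 4.27e-05) and LLC1 (2.11 ± 0.56, adjusted p = 0.00739), lines in which it was picked after its values were seen. In MC38 it stayed below the filter, with 26 reads in sgB2m and 33 in sgNT. The start of Trim69 lies 7616 bp beyond the end of B2m. The other highest changes among these genes were Lilr4b (3.46 ± 0.39), Sprr1b, Sema7a (2.92 ± 0.33), the glutathione transferase Gsta2 (2.50 ± 0.27), which has near-identical paralogs, and Lrrc10b (2.38 ± 0.33) (adjusted p at most 0.000178). Among the lowest of them were Zfp385b (-3.31 ± 0.47), the acute-phase protein Saa3 (-3.04 ± 0.45), Slc9a9 (-2.59 ± 0.12), Pard3b (-2.56 ± 0.15) and the bicarbonate transporter Slc4a4 (-2.54 ± 0.35) (adjusted p at most 0.000305). The 14 other lists tested had adjusted p between 0.0521 and 0.833. They were those of peptide loading, MHC class II, chemokines, cytokines, NK cell ligands, checkpoint ligands, NF-kB targets, cell cycle, mesenchymal, intestinal and endothelial genes, iron handling, immediate early genes and mitochondrial transcripts. Median, mean and test differed in sign for MHC class II, chemokines and NF-kB targets. The hepatocyte, alveolar, myeloid, and T and NK lists had fewer than 5 tested members.

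**Figure D2:**
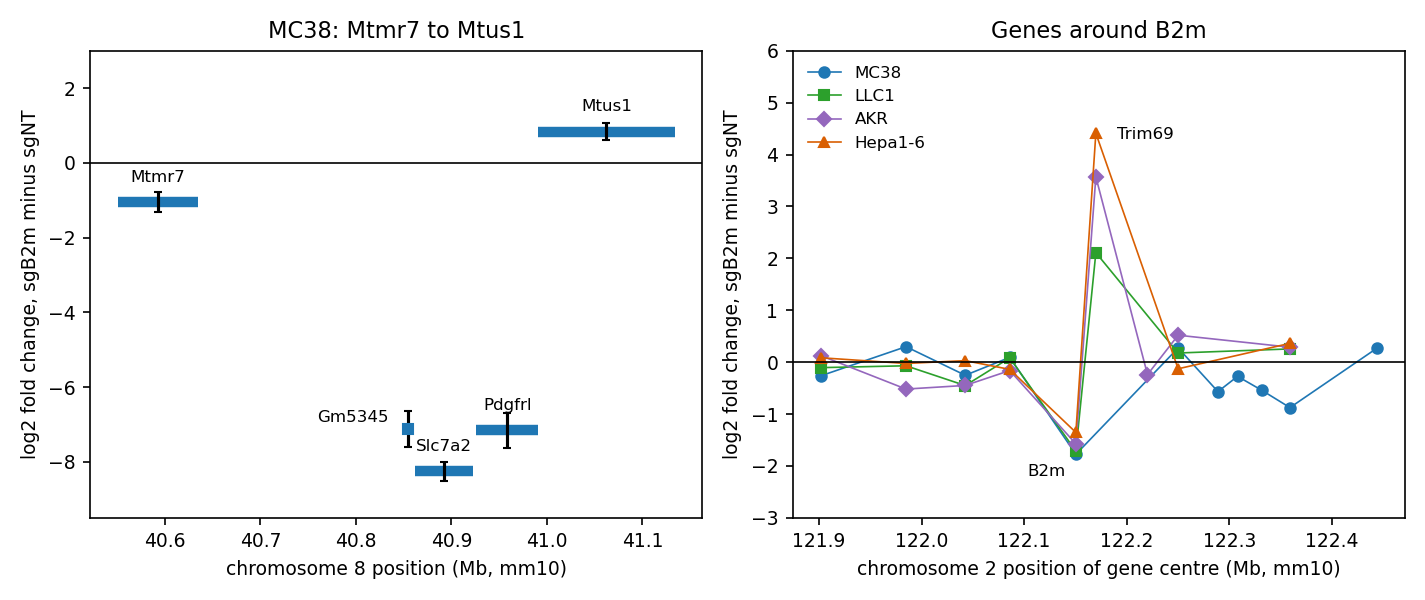
Log2 fold changes, sgB2m minus sgNT, against genome position in Mb; on the left, bars span the genes between Mtmr7 and Mtus1 on chromosome 8 in MC38 (the short Gm5345 is a square) with SE as error bars, and on the right, points are the tested genes within 300 kb of B2m in each line, joined by lines. Slc7a2 was lower by far than the 2 outer genes, Pdgfrl and Gm5345 had 0 reads in sgB2m so that their plotted values depend on the pseudocount, and Trim69 rose in LLC1, AKR and Hepa1-6 beside the lower B2m.

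In Hepa1-6 sgB2m cells, chemokines, cytokines, NF-kB targets and immediate early genes rose, and cholesterol synthesis, cell cycle and mitochondrial transcripts fell. With an estimated correlation 6 of the 12 calls held, those of chemokines, cytokines, NF-kB targets, the ATF4 response, cholesterol synthesis and immediate early genes (adjusted p at most 0.0316). The other 6, cell cycle and mitochondrial transcripts included, did not hold (0.0591 to 0.0941). The dendritic and T helper cell chemokine Ccl20 rose 71.6-fold, from 65.66 ± 15.1 to 4694 ± 234 normalised counts (6.16 ± 0.13, adjusted p = 1.71e-14). Of 14910 genes tested, 2775 rose and 2862 fell, and 408 rose and 167 fell by at least 2-fold. The groups did not overlap in 47.6% of the genes, against 10% by chance. The median absolute log2 fold change of called genes was 0.34.

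The inflammatory rise in Hepa1-6 took in the NF-kB, chemokine and cytokine lists, which share some members. Of the NF-kB targets, 20 of 21 tested members rose and 1 did not pass (20 rose adjusted over the list alone), with a median of 1.48 (camera adjusted p = 9.23e-23, and adjusted p = 0.013 with an estimated correlation). They were led by Ccl20, Saa3 (5.00 ± 0.60) and Lcn2 (4.52 ± 0.10) (adjusted p at most 7.98e-06). Of the chemokines, 10 of 15 tested members rose, 2 fell and 3 did not pass (10 rose and 2 fell adjusted over the list alone), with a median of 1.18 (camera adjusted p = 7.82e-06, and adjusted p = 0.0316 with an estimated correlation). The neutrophil chemokines Cxcl1 (3.47 ± 0.085), Cxcl5 (3.01 ± 0.059) and Cxcl2 (2.99 ± 0.12) rose, as did the monocyte chemokine Ccl2 (3.70 ± 0.18) (adjusted p at most 3.49e-10). The T cell chemokines Cxcl10 (1.22 ± 0.10) and Ccl5 (1.18 ± 0.41) and Cxcl3 (0.70 ± 0.051) rose less, and Cxcl15 (-1.34 ± 0.052) and Ppbp (-1.10 ± 0.24) fell (adjusted p at most 0.0338). Of the cytokines, 11 of 16 tested members rose and 5 did not pass (11 rose adjusted over the list alone, with camera adjusted p = 4.55e-07, and adjusted p = 0.0316 with an estimated correlation). The granulocyte factor Csf3 (5.00 ± 0.67) and Spp1 (2.01 ± 0.07) rose, and Csf2 went from 0 to 60 reads and was at least 7.58-fold higher (adjusted p at most 0.000184). The median of that list, 0.98, is the same with Csf2 at its bound.

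Immediate early genes rose with them. Of the immediate early and heat shock genes, 14 of 17 tested members rose and 3 fell (14 rose and 3 fell adjusted over the list alone), with a median of 1.06 (camera adjusted p = 9.88e-11, and adjusted p = 0.0143 with an estimated correlation). Fosb (5.34 ± 0.17), Egr1 (2.55 ± 0.04) and Ier3 (2.24 ± 0.042) led them, and Egr1 went from 1494 ± 53.6 to 8772 ± 93.8 normalised counts (adjusted p at most 1.51e-12). Of the ATF4 amino acid response, 20 of 22 tested members rose, 1 fell and 1 did not pass (21 rose and 1 fell adjusted over the list alone, with camera adjusted p = 4.68e-14, and adjusted p = 0.0133 with an estimated correlation), with Ppp1r15a (1.76 ± 0.044), Atf3 (1.74 ± 0.088) and Aldh1l2 (1.49 ± 0.11) in front (adjusted p at most 2.75e-08). Of the p53 targets, 13 of 24 tested members rose, 3 fell and 8 did not pass (13 rose and 3 fell adjusted over the list alone, with camera adjusted p = 0.00621, and adjusted p = 0.0812 with an estimated correlation), led by Plk2 (1.12 ± 0.039), the death receptor Fas (1.03 ± 0.27) and Trp53inp1 (0.74 ± 0.035) (adjusted p at most 0.00664). Of the NK cell ligands, 4 of 7 tested members rose, 1 fell and 2 did not pass (4 rose and 1 fell adjusted over the list alone, with camera adjusted p = 0.011, and adjusted p = 0.0941 with an estimated correlation), with Pvr (0.93 ± 0.037), Clec2d (0.66 ± 0.20) and Icam1 (0.66 ± 0.049) (adjusted p at most 0.014). Pvr binds activating and inhibitory receptors of NK cells, and Clec2d binds an inhibitory receptor. Type I interferon genes fell slightly, and 16 of 38 tested members fell, 4 rose and 18 did not pass (17 fell and 4 rose adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.012, and adjusted p = 0.0902 with an estimated correlation). Herc6 (-0.76 ± 0.088), Oas1a (-0.74 ± 0.054) and Isg15 (-0.57 ± 0.092) led that fall (adjusted p at most 0.000161).

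Cholesterol synthesis fell in Hepa1-6, and lists of cell cycle, mitochondrial and hepatocyte genes were called as falling at the preset correlation alone. Of the cholesterol genes, 23 of 25 tested members fell, 1 rose and 1 did not pass (23 fell and 1 rose adjusted over the list alone), with a median of -0.53 (camera adjusted p = 6.24e-17, and adjusted p = 0.0143 with an estimated correlation), led by Hmgcs1 (-0.88 ± 0.026), Mvk (-0.76 ± 0.10) and Idi1 (-0.75 ± 0.035) (adjusted p at most 1.31e-05). Of the cell cycle and replication genes, 24 of 32 tested members fell, 1 rose and 7 did not pass (24 fell and 1 rose adjusted over the list alone), with a median of -0.23 (camera adjusted p = 4.7e-09, and adjusted p = 0.0591 with an estimated correlation). The nucleotide enzymes Rrm2 (-0.80 ± 0.04) and Tyms (-0.68 ± 0.10) and the mitotic kinase Plk1 (-0.57 ± 0.051) led them (adjusted p at most 9.13e-05). Of the transcripts of the mitochondrial genome, 13 of 13 tested members fell (13 fell adjusted over the list alone, with camera adjusted p = 7.71e-15, and adjusted p = 0.0812 with an estimated correlation), with the complex I subunits mt-Nd1 (-0.87 ± 0.019), mt-Nd3 (-0.85 ± 0.038) and mt-Nd2 (-0.69 ± 0.022) (adjusted p at most 1.23e-10). The share of reads from that genome was 4.19% in sgB2m and 5.09% in sgNT. Of the hepatocyte markers, 8 of 20 tested members fell, 2 rose and 10 did not pass (8 fell and 2 rose adjusted over the list alone, with camera adjusted p = 0.00742, and adjusted p = 0.0812 with an estimated correlation), with Apoa1 (-2.52 ± 0.45), Ttr (-1.63 ± 0.084) and Ambp (-1.06 ± 0.14) (adjusted p at most 0.000381). The hepatocyte call ended under quantile normalisation (adjusted p = 0.533).

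For MHC class I in Hepa1-6, 8 of 16 tested members rose, 4 fell and 4 did not pass (8 rose and 4 fell adjusted over the list alone) in peptide loading (camera adjusted p = 0.421) and 4 of 15 tested members rose, 1 fell and 10 did not pass (4 rose and 1 fell adjusted over the list alone) in the heavy chains (camera adjusted p = 0.544). The class I transactivator Nlrc5 (1.13 ± 0.10), Tap2 (0.64 ± 0.18) and Psmb8 (0.63 ± 0.12) rose, and H2-Q1 (-1.39 ± 0.092) fell (adjusted p at most 0.00999). H2-M2 went from 0 to 40 reads and was at least 5.07-fold higher. H2-D1 (0.44 ± 0.027), picked after its value was seen, rose (adjusted p = 3.76e-09), and H2-K1 stayed below the filter. Among Hepa1-6 genes that met the same limits on expression, overlap and symbol, the highest changes were the chloride channel regulators Clca3a1, at 0 reads in sgNT, 465 in sgB2m and at least 58.5-fold higher, and its paralog Clca3b (5.50 ± 0.12), then Ccl20, Fosb, Saa3 and the nitric oxide synthase Nos2 (4.92 ± 0.60) (adjusted p at most 9.53e-06). The lowest of them were the carboxylesterase Ces1c (-5.15 ± 0.93), the Wnt antagonist Notum (-3.29 ± 0.39), Avpr1a (-3.21 ± 0.50), Cyp2c67 (-2.72 ± 0.39), Apoa1 and Arhgap36 (-2.50 ± 0.41) (adjusted p at most 0.000395). Ces1c and Cyp2c67 belong to families with close paralogs, and the call of Ces1c ended in the robust test (adjusted p = 0.0586).

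Calls near the threshold in Hepa1-6 depended on single libraries. That of Ccl5 ended without sgB2m replicate 1 (adjusted p = 0.0751) or 2 (0.157), without sgNT replicate 1 (0.12), with no filter (0.0999) and without the trend (0.0788). Those of Tap2 (0.0518) and Clec2d (0.0655) ended without sgNT replicate 3, and those of Tap2 (0.0677) and Fas (0.071) without the trend. The 14 other lists tested had adjusted p between 0.0604 and 0.842. They were those of the MHC class I parts, MHC class II, interferon-gamma GTPases, checkpoint ligands, ER chaperones, mesenchymal, epithelial, squamous, intestinal and myeloid genes, hypoxia, NRF2 targets and iron handling. Median, mean and test differed in sign for squamous and intestinal markers, hypoxia and NRF2 targets. The alveolar, endothelial, and T and NK lists had fewer than 5 tested members.

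**Figure D3:**
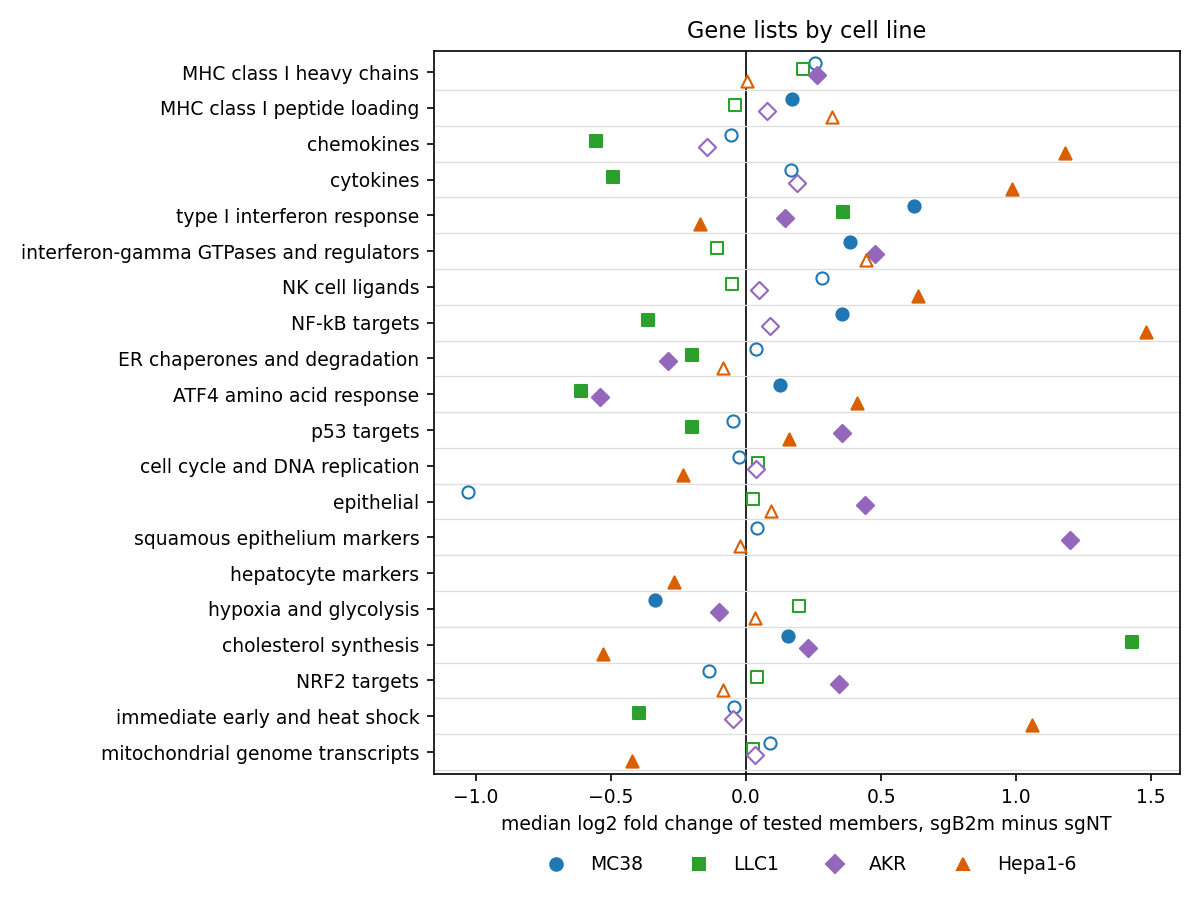
Median log2 fold change, sgB2m minus sgNT, of the tested members of each gene list called in at least 1 line; the horizontal axis is the median and each symbol is a line, filled where camera at the preset correlation called the list and open where it did not. Cholesterol synthesis ranged from 1.43 in LLC1 to -0.53 in Hepa1-6, and NF-kB targets from -0.36 in LLC1 to 1.48 in Hepa1-6.

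Few genes changed alike in the 4 lines. Of 12674 genes tested in every line, 30 rose in all 4 and 49 fell in all 4, where independent lists would share 18.4 and 24.2. Genes called in all 4 lines in any direction numbered 820 against 339 for independent calls, so the excess does not show shared directions. The genes that rose furthest in their weakest line were Peli3, Ampd3, Trp53inp1, Cebpd, Fam46b, Ly6a, Zfyve1 and Rapgef3. The ubiquitin ligase Peli3 rose by 0.91 in MC38, 1.05 in LLC1, 1.11 in AKR and 1.10 in Hepa1-6, with no difference between lines that passed the interaction test (adjusted p = 0.964). The AMP deaminase Ampd3 rose by 1.04, 0.50, 1.68 and 0.67 in the same order (interaction adjusted p = 2.73e-10), and the stem cell antigen Ly6a by 0.42, 0.71, 0.48 and 0.35 (interaction adjusted p = 0.00297). Trp53inp1 rose by 1.43, 0.50, 0.64 and 0.74, and the transcription factor Cebpd by 0.98, 0.48, 0.43 and 2.43. Fam46b rose by 0.84, 0.54, 0.85 and 0.38, Zfyve1 by 0.49, 0.34, 0.69 and 0.35, and Rapgef3 by 0.42, 0.32, 0.62 and 0.39. The adjusted p of these 8 genes was at most 0.0394 in every line. The call of Peli3 ended in MC38 without sgB2m replicate 1 (adjusted p = 0.0851) or 3 (0.0576) or sgNT replicate 2 (0.0691), and in LLC1 without sgB2m replicate 1 (0.0521). That of Cebpd ended in AKR without sgB2m replicate 2 (0.0898) or sgNT replicate 1 (0.0929). That of Fam46b ended in AKR without sgB2m replicate 2 (0.0711) or sgNT replicate 3 (0.0624), in LLC1 without any sgB2m replicate (0.0683, 0.0935 and 0.0634 for 1 to 3) or sgNT replicate 2 (0.127) or 3 (0.0683), and in Hepa1-6 without any library but sgB2m replicate 3 (0.0559 to 0.184). Other settings ended calls too. That of Peli3 ended without the trend in MC38 (0.0545) and AKR (0.0655) and with no filter in AKR (0.0589), and that of Cebpd with quantile normalisation in AKR (0.0635). That of Fam46b ended with no filter in LLC1 (0.0606) and Hepa1-6 (0.0912), and in Hepa1-6 also without the trend (0.0947) and with the replicate block (0.05).

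Besides B2m, the genes that fell furthest in their weakest line were Pde3b, Retsat, Grwd1, Shmt1, BC003965, Prmt1 and Dus3l. The phosphodiesterase Pde3b had 0 reads in MC38 sgB2m and 81 in sgNT and was at least 7.92-fold lower there, and its log2 fold change was -0.50 in LLC1, -1.01 in AKR and -0.40 in Hepa1-6. The retinol saturase Retsat changed by -0.51, -0.31, -0.33 and -0.36 in MC38, LLC1, AKR and Hepa1-6, and the folate enzyme Shmt1 by -0.52, -0.52, -0.27 and -0.35. The ribosome factor Grwd1 changed by -0.39, -0.78, -0.47 and -0.31, the arginine methyltransferase Prmt1 by -0.28, -0.49, -0.28 and -0.26, and Dus3l by -0.51, -0.41, -0.26 and -0.24. BC003965 changed by -0.29, -0.37, -0.26 and -0.27. The adjusted p of these genes was at most 0.0496 in every line. The call of BC003965 ended in MC38 without sgB2m replicate 1 (adjusted p = 0.116), 2 (0.107) or 3 (0.111) or sgNT replicate 3 (0.159), and in Hepa1-6 without sgB2m replicate 2 (0.154) or sgNT replicate 2 (0.0959) or 3 (0.0894). That of Dus3l ended in AKR without sgNT replicate 1 (0.0511), and in Hepa1-6 without sgB2m replicate 1 (0.0819) or 3 (0.0688) or sgNT replicate 1 (0.139) or 3 (0.0525). Other settings ended calls too. That of BC003965 ended in MC38 with the replicate block (0.0531), quantile normalisation (0.0583), no filter (0.0806) and no trend (0.0973), in Hepa1-6 with no filter (0.0849) and no trend (0.112), and in LLC1 with no trend (0.0553). Without the trend, the calls of Prmt1 in MC38 (0.0605) and Dus3l in LLC1 (0.0616) ended.

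With the line as the replicate, limma called 0 genes as changed in a single direction, also on voom values. Fewer genes than chance gives (560) had an unadjusted p under 0.05. The edited B2m ranked first but was not called (adjusted p = 0.11), so shared changes are not ruled out. Pearson correlations of log2 fold changes across genes ran from -0.18 (LLC1, Hepa1-6) to 0.14 (LLC1, AKR) over 6 pairs. Genes are not independent replicates. The change differed between lines for 8848 genes, 69.8% of those tested (interaction test). Lists that passed in opposite directions in 2 lines formed 17 pairs over 8 lists, and the interaction itself passed for each pair, with adjusted p of at most 0.0221 with an estimated correlation. At the preset correlation, cholesterol synthesis rose in MC38, LLC1 and AKR and fell in Hepa1-6. Its calls held with an estimated correlation in LLC1 (adjusted p = 0.0221) and Hepa1-6 (0.0143), and not in MC38 (0.0663) or AKR (0.185). The ATF4 response rose in MC38 and Hepa1-6 and fell in LLC1 and AKR. Its calls held with an estimated correlation in Hepa1-6 (0.0133) and LLC1 (0.0221), and not in MC38 (0.272) or AKR (0.185). NF-kB targets rose in MC38 and Hepa1-6 and fell in LLC1. With an estimated correlation that call held in Hepa1-6 (0.013) and not in MC38 (0.272) or LLC1 (0.0812). Type I interferon genes rose in MC38, LLC1 and AKR and fell in Hepa1-6. With an estimated correlation that call held in MC38 (0.0407) and not in LLC1 (0.0812), AKR (0.204) or Hepa1-6 (0.0902).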

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

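The tests on Trim69, on copy number, on the Slc7a2 segment and on culture handling were chosen after the results were seen. The items of the next 2 paragraphs were picked out because the change from sgNT to sgB2m differed between cell lines by a test of the difference itself. The 3 patterns after them were picked for weighing after the tables were seen. The test of the difference uses the spread between the 3 libraries of a group, and guide and population share the same split. It therefore cannot tell an effect of the guide from other differences between the 2 populations of a line.

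The fall of B2m differed in size between lines (interaction adjusted p = 1.13e-05), with log2 fold changes of -1.78 in MC38, -1.71 in LLC1, -1.57 in AKR and -1.35 in Hepa1-6, and the same direction in 24 of 24 libraries. Cxcl16 differed in direction (interaction adjusted p = 1.32e-08), from -1.99 in AKR to 1.61 in Hepa1-6. Of the 12674 genes tested in every line, 8848 differed between lines. Of the 112 named genes tested in every line, 103 did. Most of these genes were picked for a large change in some line, so that share says little.

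Gene lists called in opposite directions formed 17 pairs of lines, and the difference was tested for each with camera. NF-kB targets differed between MC38 and LLC1 (adjusted p = 2.18e-05) and between LLC1 and Hepa1-6 (7.21e-14). The ATF4 amino acid response differed between MC38 and LLC1 (1.04e-14), MC38 and AKR (2.24e-12), LLC1 and Hepa1-6 (3.21e-17), and AKR and Hepa1-6 (1.56e-20). Cholesterol synthesis differed between Hepa1-6 and each of MC38 (5.96e-19), LLC1 (5.77e-34) and AKR (3.21e-17). Type I interferon genes differed between Hepa1-6 and each of MC38 (1.14e-08), LLC1 (6.97e-05) and AKR (0.00346). The p53 targets differed between LLC1 and AKR (1.22e-07) and between LLC1 and Hepa1-6 (0.00262). Chemokines (8.01e-05), cytokines (6.69e-06) and immediate early genes (2.52e-11) differed between LLC1 and Hepa1-6.

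Trim69, the next gene downstream of B2m, rose in LLC1, AKR and Hepa1-6. Copy gain of the whole segment around B2m is argued against by the other tested genes within 300 kb, whose median log2 fold change was 0.0059 in LLC1, -0.16 in AKR and 0.0017 in Hepa1-6. Beyond Trim69, Sord changed by 0.176, 0.519 and -0.128 and Shf by 0.255, 0.288 and 0.362 in LLC1, AKR and Hepa1-6. Rps12-ps10, tested there in AKR alone, changed by -0.24. A median over both sides cannot speak to a gain on the Trim69 side alone, which was not tested. Some TRIM family genes respond to interferon. In Hepa1-6, 4 of 38 type I interferon genes rose and 16 fell (median -0.17, adjusted p = 0.0902 with an estimated correlation). Of the interferon-gamma GTPases and regulators there, 13 of 25 tested members rose and 5 fell (median 0.445, camera adjusted p = 0.0604, and 0.379 with an estimated correlation). The type I list thus showed no rise, but an interferon source in Hepa1-6 stays open. In LLC1 and AKR the type I list rose (medians 0.36 and 0.15, adjusted p = 0.0812 and 0.204 with an estimated correlation), and that source was not tested. Transcription running on from the edited B2m gene may have raised Trim69, and the 602 reads of Trim69 in the 9 sgB2m libraries cannot be placed within the gene from a table of counts. That explanation stays open, as does a different origin in each line.

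Changes in MC38 depended on the position of the genes. The SD of the chromosome medians was 0.103, above the highest of 1000 shuffles (0.0226), and copy-number differences between the 2 populations are a candidate explanation. A trend on GC content and transcript length is argued against as the whole cause, since the SD was 0.0956 after its removal, above the highest of 1000 shuffles (0.0242). The SD also passed the highest shuffle in LLC1 (0.0596 against 0.0233) and by less in AKR (0.0299 against 0.0273), but not in Hepa1-6 (0.0225 against 0.0226). Loss of the segment from Slc7a2 to Pdgfrl stays open, since 0.32% of the sgNT level of Slc7a2 remained in sgB2m on 34 reads, where a first limit of 3 reads per library (mean 11.3, lowest 8) counted against a complete loss and was replaced, after the value was seen, by an assumed allowance of 1% for reads carried over from other libraries.

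Chemokine, NF-kB and immediate early genes rose in Hepa1-6. Myeloid cells among the sgB2m cells are argued against, since 9 of 15 myeloid markers stayed under a log2 value of 3.5 in every sgB2m library, Ptprc and Fcer1g reached at most 2.34 and 1.6, and Lyz2 (5.02 to 5.46) stayed in the range of sgNT (4.57 to 5.53). Of the 5 tested myeloid markers 3 rose (median 1.12): Cd68, Cd14 and Mrc1 were higher in sgB2m, as such cells would give, and Csf1r was lower. Culture density or handling that differed between the 2 populations may explain the pattern as well as the guide, since the cell cycle list fell with it (camera adjusted p = 4.7e-09, and 0.0591 with an estimated correlation) and guide and population share the same split. These explanations cannot be told apart, and an effect of B2m loss itself stays untested beyond the comparison of guides.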

How the results depend on the processing

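Only the analysis of MC38 without chromosomes 1 and 18 was chosen after the data were examined. No named gene and no called list reversed its direction under any alternative. Of all called genes, 4 in MC38, 9 in LLC1, 10 in AKR and 10 in Hepa1-6 had the other sign with quantile normalisation. Whether more of the called genes rose or fell was near even and not tested, and it turned under at least 1 alternative in each line. Among those changed at least 2-fold, 574 rose and 405 fell in MC38, 333 and 314 in LLC1, 436 and 373 in AKR, and 408 and 167 in Hepa1-6. That balance was not tested either. Of the 251 named gene values (a gene in a line), 251 stayed past the threshold with a pseudocount of 8, median centring and voom, and 226 of 226 that could be tested did so with the stricter filter. Calls ended for 17 without the trend, 12 without the filter, 2 with quantile normalisation, 2 with the replicate block, 1 with the robust test, and 51 of 1434 with a library left out. Of the 39 list calls, 30 ended with an estimated correlation, 7 with quantile normalisation, 3 with the stricter filter, 2 without the filter, 1 with median centring, 1 with the replicate block and 0 with fry, and 7 of 234 with a library left out.

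With the stricter filter, genes changed at least 2-fold numbered 567 in MC38, 314 in LLC1, 428 in AKR and 317 in Hepa1-6, since fewer genes were tested. With the test against 2-fold they numbered 237, 82, 70 and 126 in the same order, since that test asks for a change shown to exceed 2-fold. Lists called with an estimated correlation numbered 1 in MC38, 2 in LLC1, 0 in AKR and 6 in Hepa1-6, and with fry, which tests each list by itself, 15, 14, 21 and 22. With quantile normalisation, 6 lists were called in AKR; the cause was not tested. Genes called in the same direction in all 4 lines numbered 42 with no filter and 20 without the trend, and of these 42 and 19 were among the 79. Genes with 1 direction across lines numbered 1 with the stricter filter and 1 with a pseudocount of 8. These causes were not tested.

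With a library left out, genes called ranged from 3858 to 6082 in MC38, 5623 to 6163 in LLC1, 5733 to 6657 in AKR and 4790 to 5058 in Hepa1-6. Those changed at least 2-fold ranged from 778 to 1024, 556 to 612, 712 to 801 and 502 to 537, and lists from 7 to 9, 8 to 9, 8 to 13 and 12 to 13. In MC38 the 6082 calls came without sgNT replicate 1, and no other library left out gave more than 4392. Of the MC38 genes changed at least 2-fold, 263 to 384 fell and 409 to 708 rose, against 405 and 574 with all libraries. The log2 fold change of B2m ranged from -1.81 to -1.75 in MC38, -1.73 to -1.70 in LLC1, -1.64 to -1.54 in AKR and -1.38 to -1.32 in Hepa1-6. That of Cxcl16 ranged from -0.79 to -0.59, -1.28 to -0.86, -2.21 to -1.68 and 1.51 to 1.68. For Cxcl16 in AKR only 3 of 6 such runs gave a value, and the stricter filter gave none. Genes in the same direction ranged from 61 to 92, genes that differed between lines from 8573 to 8970, and genes with 1 direction stayed at 0.

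The replicate block was fixed as an alternative, and not as the main test, before the data were examined. Replicate numbers then showed little pairing: correlations of deviations between libraries with the same number ranged from -0.028 to 0.051. Even so, in LLC1 3 of 3 sgB2m libraries correlated best with the sgNT library of their own number, as did 2 in Hepa1-6 and 1 in each of MC38 and AKR. With the block, 5120, 6306, 6494 and 5589 genes were called in MC38, LLC1, AKR and Hepa1-6. Depth of 25 to 49.7 M reads limits genes near the filter, such as Cxcl16 in AKR at 20 and 84 reads.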

Other observations

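The genes in the next 2 paragraphs were chosen from the lists after their values were seen; the tests below on directions and regroupings were planned. As a list, co-stimulatory and checkpoint ligands differed in 0 of 6 pairs of lines by camera (adjusted p from 0.655 to 0.978, lowest unadjusted p 0.497), and the values below are of single genes. Cd274, which encodes PD-L1, rose in Hepa1-6 (1.17 ± 0.13, adjusted p = 4.16e-06) and fell in LLC1 (-0.60 ± 0.13, adjusted p = 0.00162). It did not pass in MC38 (0.91 ± 0.33, adjusted p = 0.058) or AKR (0.24 ± 0.12, adjusted p = 0.151), and its change differed between lines (interaction adjusted p = 0.000101). Nt5e, the adenosine-forming CD73, fell in MC38 (-3.52 ± 0.36) and LLC1 (-0.72 ± 0.14) and rose in AKR (0.94 ± 0.18) and Hepa1-6 (0.66 ± 0.057). The death receptor Fas rose in MC38 (2.51 ± 0.14). Cd74, the class II invariant chain, fell in LLC1 (-2.19 ± 0.39) and AKR (-1.24 ± 0.088) and rose in Hepa1-6 (1.75 ± 0.52).

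Of the mesenchymal and matrix genes, 11 rose and 6 fell in MC38, 8 and 9 in LLC1, 4 and 11 in AKR, and 3 and 3 in Hepa1-6. The list passed camera in 0 lines (1 at an unadjusted p under 0.05, AKR) and limma's fry in 4, and of 6 pairs of lines 1 differed, AKR and Hepa1-6 (adjusted p = 0.037, and 0.0995 with an estimated correlation). The values below are of single genes. In MC38, Thbs1 (4.31 ± 0.041), Acta2 (2.63 ± 0.22) and Col1a1 (1.59 ± 0.057) rose and Col1a2 (-1.21 ± 0.047) fell. In LLC1, Col3a1 rose (1.29 ± 0.021), and in AKR, Fn1 (-1.35 ± 0.065) and Col1a1 (-1.05 ± 0.085) fell. The transferrin receptor Tfrc fell in MC38 (-0.55 ± 0.063), LLC1 (-0.57 ± 0.04) and AKR (-0.71 ± 0.058), and did not pass in Hepa1-6 (-0.093 ± 0.04, adjusted p = 0.0827). In AKR, the ferritin Ftl1 (1.28 ± 0.045) and the reductase Steap3 (1.40 ± 0.12) rose.

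The hypothesis that genes called in every line share a direction was tested. Of 820 such genes, 9.63% had 1 direction, against a median of 12.4% and a range of 9.51% to 16.3% in 1000 draws that shuffled the signs within each line. A shared direction beyond independent ones was therefore not seen. The share was within the range but near its lower end, with 2 of the 1000 draws at or below it, so directions may have differed between lines more often than independence gives.

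Each line allows 10 splits of its 6 libraries, too few for a share under 0.05. Genes called numbered 5251 in MC38, 6503 in LLC1, 6815 in AKR and 5637 in Hepa1-6, and at most 2, 1, 1 and 2 in another split; 1 split, the real one, reached the real count in each line. The 2-fold counts of 979, 647, 809 and 575 stood against at most 2, 1, 1 and 2. Lists called numbered 7, 9, 11 and 12 against at most 7, 6, 3 and 7 in another split, so that in MC38 another split gave as many lists and 2 of 10 reached the real count. Over 100 regroupings within lines, the real one included, 1, the real one, reached the count of 8848 genes that differed between lines (highest other 5759). A regrouping breaks the split between guides within lines, so this largely follows from the counts per line. It does not test whether a change was equal in all lines. For the 79 genes in the same direction, 1 regrouping, the real one, reached the count (highest other 0), but other splits of a line call at most 2 genes, so this repeats the counts per line and says nothing of shared direction. All 100 reached the count of 0 genes with 1 direction (highest other 1), as any regrouping must, so that comparison tests nothing.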
